A study of Mus musculus with 20 samples.

How the data were processed

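Each of the 20 libraries was made from a pool of 10 mouse blastocysts that had been microinjected as zygotes and cultured in vitro. The labels give 3 groups: vehicle (n = 7), a let-7f-5p mimic at a concentration tied to paternal stress, called Str let-7f (n = 8), and the mimic at the doubled concentration, called 2x Str let-7f (n = 5). Total RNA was depleted of ribosomal RNA and made into stranded libraries with a low-input kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, kallisto 0.50.1, DESeq2 1.48.2, FastQC 0.12.1, MultiQC 1.28 and the genome build GRCm39. They do not say how transcripts were summed to genes or which annotation was used.

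The deposited values are a normalized count per gene, a signal that is never negative, and per the labels' protocols no other unit was given. The file itself was checked: in every library 100% of the values were whole multiples of the value of 1 read within a tolerance of 0.01, so whole reads and library depths were recovered. The authors' table lists 16014 named genes, each with at least 10 reads in at least 5 libraries, and 1 entry without a gene name. That entry held 0.0286% to 0.0618% of the reads of a library and was left out of depths and tests. kallisto divides reads among near-identical transcripts, so values of single members of multigene families are uncertain.

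Depth ran from 1.54 M to 58.8 M reads per library, a ratio of 38.1, and 3 reads corresponded to 0.0511 to 1.94 reads per 1 M reads in single libraries. Such floors cover counting error only, since reads were amplified. Depth did not separate the groups (exact permutation p = 0.883 for Str let-7f against vehicle, 0.538 for 2x Str let-7f against vehicle and 0.632 for 2x Str let-7f against Str let-7f, two-sided). Counts of the 59 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom at least 16.8), so no library was counted as a repeat of another.

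The groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Normalized counts were taken as log2(value + 1) for the 15068 genes with at least 10 in at least 5 libraries. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 20 libraries with a trended prior, and calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A fold change is therefore on the log2(value + 1) scale and understates changes of low genes. Limma's camera with a preset correlation of 0.01 tested 33 gene lists per comparison, adjusted over the lists, and was repeated with an estimated correlation. The whole profile was compared by an exact permutation test of a pseudo-F over Euclidean distances. Agreement between both concentrations was set beside 100 simulated draws of unchanged groups and beside 35 splits of the vehicle libraries into disjoint sets.

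Named genes were the 10 with the smallest adjusted p in each direction, without predicted gene models, clone names and pseudogenes, up to 4 members of each list with the smallest p, and Lin28a, Lin28b, Hmga2, Trim71, Igf2bp1, Arid3a, Ddx3y and Eif2s3y. Where no gene passed in a direction, the 5 with the smallest p were taken as values that did not pass. Genes named outside this rule are marked as such. Xist, which the rule also named, was not in the table used here.

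A reference of another build, GENCODE M21 on GRCm38, was used only for gene names, pseudogene types and 3′ untranslated region (UTR) sequence, and no genome coordinates are given. Of the genes, 14919 matched by symbol, 311 by an older symbol and 784 did not match. Of 14000 genes with an annotated 3′ UTR, 526 held the 8-base let-7 site CTACCTCA, and 406 other 8-base sequences of the same bases served as controls.

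Alternatives included other pseudocounts, filters, scalings, array weights, the Y-linked level as a covariate, the replicate number as a block, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Adjusted p-values that DESeq2 left undefined stayed so. On simulated counts with known changes, the limma step recovered 6.2%, 41.5% and 68.9% of genes changed 1.5-fold, 2-fold and 4-fold for Str let-7f against vehicle (14875 genes), with 3.9% false calls. For 2x Str let-7f against vehicle (14837 genes) it recovered 6.3%, 28.1% and 71.9%, with 10.5% false calls. For 2x Str let-7f against Str let-7f (14863 genes) it recovered 3.1%, 29.9% and 60% with 7.6% false calls. The labels do not say whether pools of a group came from separate females or injection days, so p-values measure the spread between these pools.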

Results

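The series asked how a raised level of the microRNA let-7f-5p in the zygote alters the blastocyst transcriptome. The injected mimic had the sequence UGAGGUAGUAGAUUGUAUAGUU, and vehicle pools received the nuclease-free water in which it was dissolved. Zygotes were wild type, of a strain labelled F1 C57BL/6Jx129S1/SvlmJ. RNA sequencing covered 7 vehicle pools with 3.30 to 46.6 M reads (median 10.5), 8 Str let-7f pools with 1.54 to 58.8 M (median 12.4) and 5 2x Str let-7f pools with 1.94 to 27.2 M (median 5.04). No group received an unrelated mimic, and the labels name no injection day or library batch. The libraries under 2 M reads were Str let-7f replicate 9 and 2x Str let-7f replicate 4. In vehicle replicate 5, 5.39% of reads fell on Lars2, against 0.637% to 1.94% in the other vehicle pools.

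Whole profiles of blastocysts that had received the mimic differed from vehicle profiles by more than pools of 1 group differed among themselves. The pseudo-F was 1.75 for Str let-7f (exact permutation p = 0.000466, 6435 splits) and 1.71 for 2x Str let-7f (exact p = 0.00126, the smallest that 792 splits can give). Between both mimic groups it was 0.902 (exact p = 0.869, 1287 splits). Across genes, which are not independent, pairs of pools of 1 group correlated with a median Pearson r of 0.902 in vehicle, 0.886 in Str let-7f and 0.892 in 2x Str let-7f. The mean log2 level of 4 Y-linked genes, a measure of the share of male embryos in a pool, differed by 0.16 in Str let-7f against vehicle (exact permutation p = 0.505) and by -0.01 in 2x Str let-7f (exact permutation p = 0.96).

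Known targets of let-7 were lower in Str let-7f blastocysts than in vehicle blastocysts. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, fell from 1597 ± 234 normalized counts (SD, n = 7) to 605 ± 180 (n = 8), a log2 fold change of -1.44 ± 0.19 (SE; limma adjusted p = 8.21e-05). Trim71, a ubiquitin ligase and RNA-binding protein of early embryos, fell from 1828 ± 142 to 1069 ± 235 (-0.80 ± 0.14, limma adjusted p = 0.00207). Igf2bp1, an mRNA-binding protein, fell from 4049 ± 305 to 2729 ± 334 (-0.57 ± 0.10, limma adjusted p = 0.0021). For these 3 genes all 8 pools lay below every vehicle pool. The orphan nuclear receptor gene Nr6a1 fell by 1.70 ± 0.34 on the log2 scale (limma adjusted p = 0.00568), with 6 of 8 pools below every vehicle pool. Of 45 measured members of the let-7 target list, 5 fell and 0 rose, or 9 and 0 adjusted over the list alone. The list was lower as a group, with a median log2 fold change of -0.29 (camera adjusted p = 1.89e-05, and adjusted p = 0.0011 with an estimated correlation). Lin28b, at 21.99 ± 11.35 against 39.1 ± 12.3 normalized counts, did not pass (limma adjusted p = 0.283), and neither did Arid3a (-0.45 ± 0.41, limma adjusted p = 0.671). Hmga2, a chromatin protein gene with a long-known let-7 response, stood at 2260 ± 309 against 2116 ± 385 (limma adjusted p = 0.784).

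**Figure D1:**
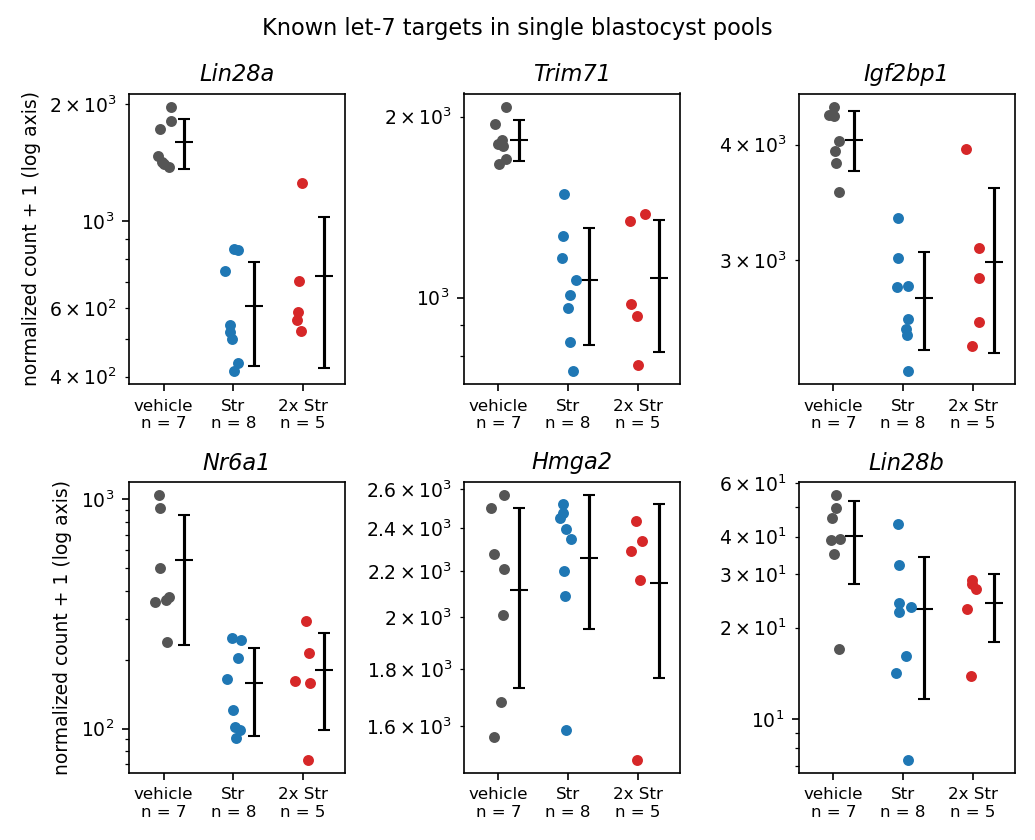
Normalized count plus 1 (log axis) of Lin28a, Trim71, Igf2bp1, Nr6a1, Hmga2 and Lin28b in each pool of 7 vehicle, 8 Str let-7f and 5 2x Str let-7f pools, with mean and SD beside the points. Lin28a and Trim71 lie below every vehicle pool in all pools of both mimic groups, and Hmga2 overlaps across the groups.

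Among the genes with the smallest adjusted p in Str let-7f blastocysts, Ppl, which encodes the cytoskeletal linker periplakin, rose from 286 ± 79.4 to 1463 ± 257 normalized counts (2.38 ± 0.15, limma adjusted p = 1.82e-09). Gpnmb, a transmembrane glycoprotein gene, rose from 29.0 ± 26.2 to 626 ± 213 (4.67 ± 0.35, limma adjusted p = 2.35e-08), and the nonmuscle myosin gene Myh14 from 42.8 ± 23.9 to 653 ± 393 (3.86 ± 0.34). Me1, the cytosolic malic enzyme that makes NADPH, rose from 1006 ± 148 to 2813 ± 542 (1.47 ± 0.12), and the creatine kinase gene Ckb from 3245 ± 269 to 6529 ± 790 (1.00 ± 0.09). Dmkn, Itpr3 and Eppk1 rose by 1.92, 1.15 and 1.82, and Ccng1 by 1.02. The carbonyl reductase gene Cbr2 had 11 reads in 3 vehicle libraries together and 892 reads over all 8 Str let-7f libraries (5.603 ± 0.57). Nid2, which encodes the basement membrane protein nidogen-2, fell from 1320 ± 261 to 324 ± 92.6 (-2.05 ± 0.18, limma adjusted p = 1.79e-07). Lower as well were Podxl (-2.68 ± 0.43), Rcn1 (-1.34 ± 0.23), Trim6 (-1.18 ± 0.18), Acsl6 (-1.11 ± 0.16), Ckap4 (-0.95 ± 0.15) and Golm2 (-0.82 ± 0.12). In all 20 genes taken by smallest adjusted p, every Str let-7f pool lay on 1 side of all vehicle pools, except for Lamc1 (7 of 8). The genes were chosen by p in these same pools, so this separation follows largely from the choice and adds no support.

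**Figure D2:**
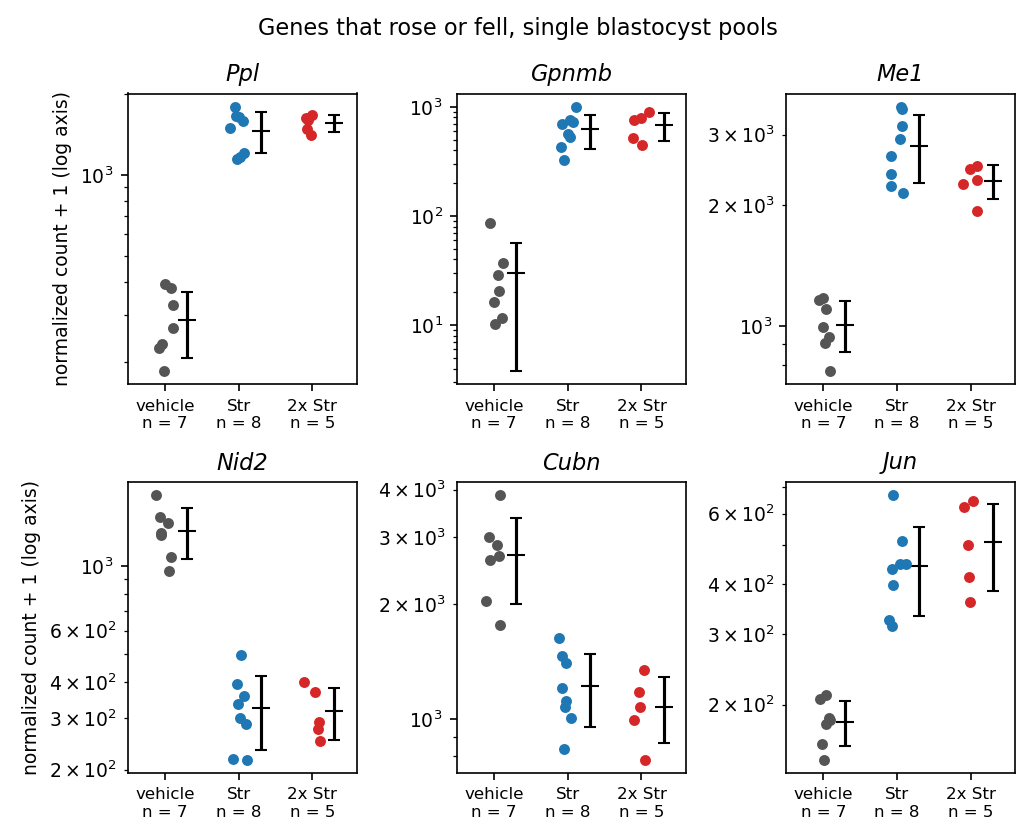
Normalized count plus 1 (log axis) of Ppl, Gpnmb, Me1, Nid2, Cubn and Jun in each pool of 7 vehicle, 8 Str let-7f and 5 2x Str let-7f pools, with mean and SD beside the points. In all 6 genes, which were chosen by p in these same pools, the pools of both mimic groups lie apart from the vehicle pools.

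Primitive endoderm genes, which mark the inner cell mass lineage that goes on to form yolk sac endoderm, were lower in Str let-7f blastocysts. Of 24 measured members, 12 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 4.86e-15, and adjusted p = 0.0122 with an estimated correlation). Cubn, an endocytic receptor, fell from 2690 ± 684 to 1218 ± 265 normalized counts (-1.13 ± 0.16, limma adjusted p = 0.000241). The laminin genes Lamc1 and Lamb1 fell from 13710 ± 2638 to 6903 ± 2005 (-1.01 ± 0.17) and from 9727 ± 1493 to 5212 ± 1489 (-0.94 ± 0.17). Sparc, a matrix glycoprotein gene, fell from 3067 ± 477 to 1654 ± 534 (-0.94 ± 0.18). Gata6, Pdgfra and Sox17, named after their values were seen as genes active early in this lineage, did not pass, at 0.32 ± 0.18, -0.37 ± 0.17 and -0.21 ± 0.18 on the log2 scale. The epiblast and pluripotency list (27 measured, median 0.03, camera adjusted p = 0.916) and the trophectoderm list (28 measured, median 0.02, camera adjusted p = 0.578) did not pass. Within the epiblast list Tfcp2l1 rose by 0.29 ± 0.08 on the log2 scale. Within the trophectoderm list Krt19 rose by 1.67 ± 0.38 and Lgals3 by 0.98 ± 0.25. The call of Tfcp2l1 was lost on leaving out any of 12 of 15 libraries (highest limma adjusted p = 0.1, without vehicle replicate 1) and that of Lgals3 on leaving out any of 5 (highest 0.0768, without vehicle replicate 3). Krt19 (limma adjusted p = 0.0764) did not pass in the libraries over 5 M reads, a subset chosen after seeing the data.

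**Figure D3:**
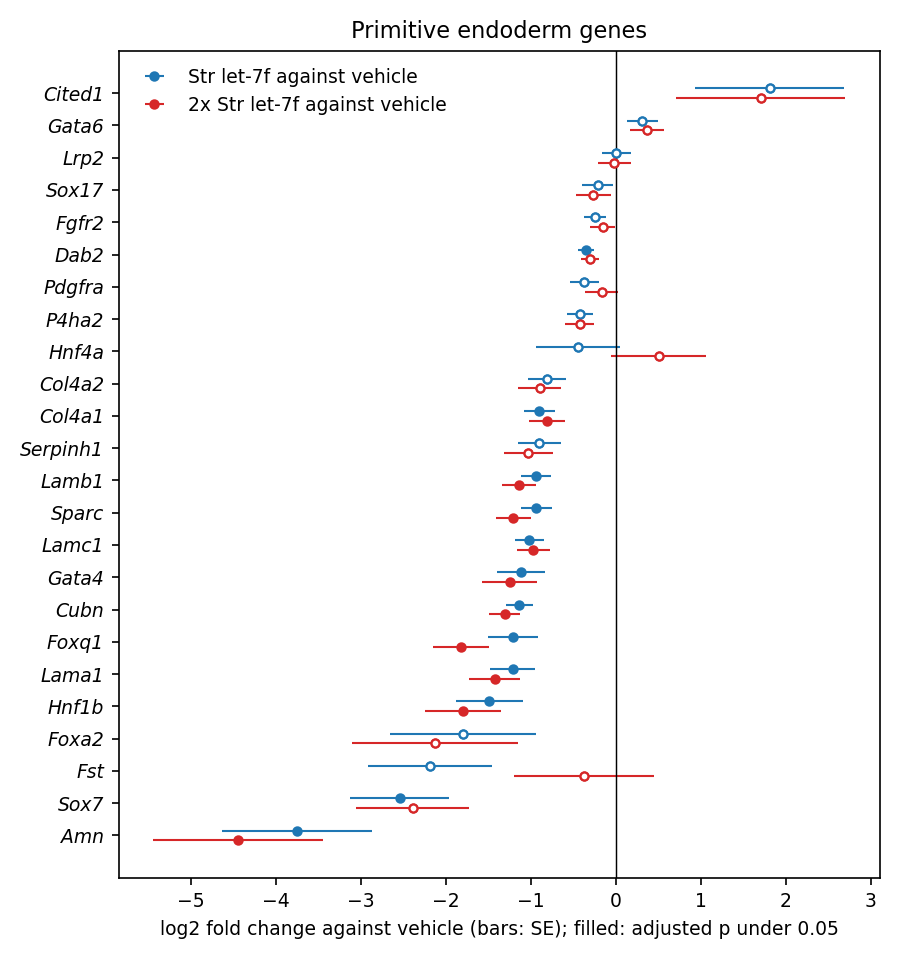
Log2 fold change against vehicle of the 24 measured primitive endoderm genes in Str let-7f (n = 8) and 2x Str let-7f (n = 5) blastocysts, against 7 vehicle pools, with bars for the SE and filled points for an adjusted p under 0.05. Of the 24, 12 fell in Str let-7f and 10 in 2x Str let-7f.

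Transcripts of the 2-cell stage, which mark the first wave of embryonic genome activation and are normally shut off long before the blastocyst, were higher in Str let-7f pools. Over the 16 measured members of the list, 127 reads per 1 M reads (RPM) were counted in Str let-7f and 30.6 in vehicle. This is a pooled ratio of 4.16, weighted by depth, and the median Str let-7f pool stood at 91.85 RPM. Of 8 pools, 6 lay above every vehicle pool (exact permutation p = 0.00761, two-sided). Here and for the other RPM sums, that test compared the mean log2(RPM + 1) per pool, not the pooled ratio. As a list they were higher (median log2 fold change 2.28, camera adjusted p = 2.69e-07), but adjusted p = 0.14 with an estimated correlation. Genes needed at least 10 in at least 5 libraries, so members without vehicle reads could enter only through mimic pools. The list median, its rate and its test are therefore partly set by that filter, at both concentrations. With members at 0 reads in vehicle set to their bound, the median was 2.79. Of the members, 1 rose over all genes tested and 11 adjusted over the list alone. That gene was Usp17le, a deubiquitinase gene (3.98 ± 0.92, limma adjusted p = 0.0175), with 9 reads in 1 vehicle library and 619 in Str let-7f. It did not pass in the libraries over 5 M reads (limma adjusted p = 0.13). Tcstv3, Tdpoz4, Usp17lb, Zscan4c and Zscan4d had no reads in any vehicle library and 1661 reads in Str let-7f, at least 529-fold higher over a floor of 3 reads in the vehicle group. These 5 were singled out after their values were seen, and 2 of 8 Str let-7f pools had no reads of them either. Reads of single copies in these multigene families are uncertain, so the Zscan4, Usp17l and Tcstv families were also summed. Pooled over libraries they stood at 82.4 against 7.35 RPM (exact permutation p = 0.0295). Copies without vehicle reads could enter this sum, too, only through mimic pools, at both concentrations. The rise was uneven, with a median Str let-7f pool at 46.6 RPM and 5 of 8 pools above every vehicle pool. In the same pools Ooep and Khdc3, genes of the maternal subcortical complex of the egg, rose by 1.04 ± 0.21 and 0.52 ± 0.12. The oocyte and maternal list as a whole (12 measured) did not pass (median 0.20, camera adjusted p = 0.523, mean log2 fold change -0.05). Its member Kpna7 fell, with 4 reads in 1 Str let-7f library against 261 reads in vehicle. On leaving out single libraries, Kpna7 was tested in only 11 of 15 cases. It did not pass without vehicle replicate 3 (limma adjusted p = 0.0508). Khdc3 did not pass in the libraries over 5 M reads (limma adjusted p = 0.06).

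**Figure D4:**
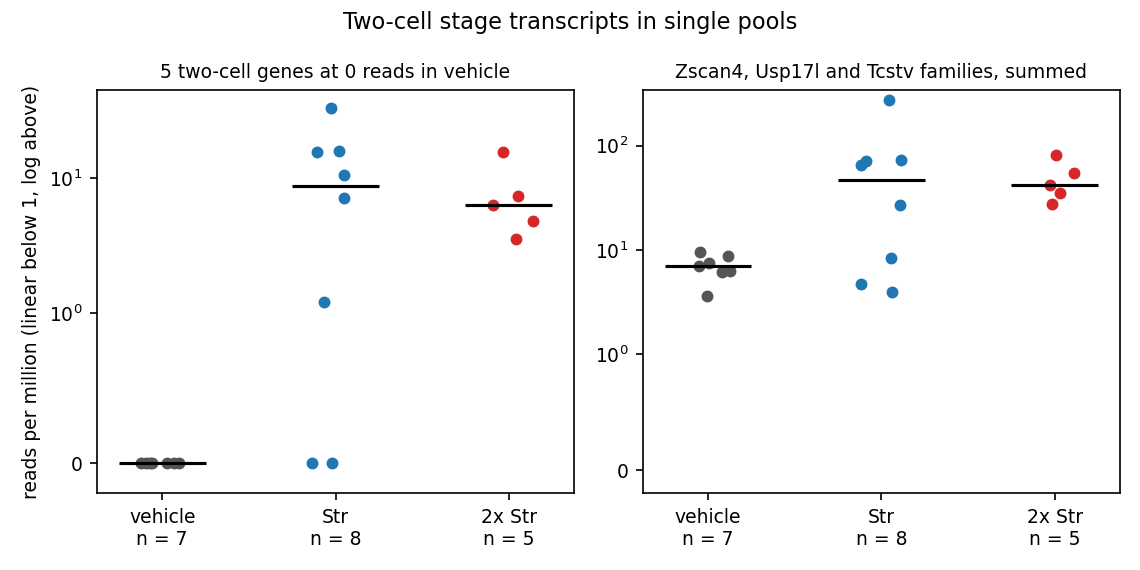
Reads per 1 M reads (RPM, linear below 1, log above) in each of 7 vehicle, 8 Str let-7f and 5 2x Str let-7f pools, with lines at the medians, of 5 genes of the 2-cell stage at 0 reads in vehicle, left, and of the Zscan4, Usp17l and Tcstv families summed, right. On the right, Str let-7f pools run from 3.92 to 273 and vehicle pools from 3.64 to 9.60.

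Heat shock and oxidative stress genes and p53 targets were higher as groups in Str let-7f blastocysts, though for each list adjusted p = 0.11 with an estimated correlation. Of 27 measured heat shock and oxidative stress genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.19 (camera adjusted p = 0.000294, but adjusted p = 0.11 with an estimated correlation). Txnrd1, which encodes thioredoxin reductase, rose from 924 ± 115 to 1550 ± 218 normalized counts (0.74 ± 0.12, limma adjusted p = 0.000848), and Gclc, of glutathione synthesis, from 198 ± 67.4 to 437 ± 162 (1.13 ± 0.24). The chaperone genes Hspb1 (0.68 ± 0.16) and Dnaja1 (0.54 ± 0.13) rose as well. Of 24 measured p53 targets, 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.000294, but adjusted p = 0.11 with an estimated correlation). The cyclin G1 gene Ccng1 rose from 1200 ± 233 to 2426 ± 389 (1.02 ± 0.12, limma adjusted p = 3.1e-05). Perp rose by 0.55 ± 0.11, Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 0.74 ± 0.19 and Btg2 by 0.79 ± 0.22. Another stress list, the integrated stress and unfolded protein response, did not pass and lay lower (24 of 29 members below 0, median -0.12, camera adjusted p = 0.194). The immediate early genes Jun (180 ± 23.3 to 444 ± 112, limma adjusted p = 0.00014) and Fos (12.3 ± 8.35 to 56.1 ± 27.4, limma adjusted p = 0.0323) rose, while their list, FGF and ERK targets (18 measured), did not pass (median 0.00, camera adjusted p = 0.484). Calls were lost on leaving out vehicle replicate 6 for Hspb1 (limma adjusted p = 0.0546), Cdkn1a (0.0777) and Btg2 (0.114), vehicle replicate 3 for Dnaja1 (0.0684) and Str let-7f replicate 7 for Fos (0.0638). In all, these calls were lost in 3, 9, 11, 5 and 5 of 15 cases. Apart from Cdkn1a and Btg2, the other cases were vehicle replicate 8 and Str let-7f replicate 6 for Hspb1, vehicle replicates 1 and 2 and Str let-7f replicates 6 and 10 for Dnaja1, and vehicle replicate 1 and Str let-7f replicates 1, 5 and 9 for Fos. Gclc (limma adjusted p = 0.0732) and Perp (limma adjusted p = 0.0636) did not pass in the libraries over 5 M reads.

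Smaller shifts were seen in 5 other lists in Str let-7f. Of 43 measured DNA methylation and chromatin modifier genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.00099, and adjusted p = 0.0182 with an estimated correlation). They included Dnmt3l, a cofactor of de novo DNA methylation (-0.88 ± 0.20, limma adjusted p = 0.0132), and the methyltransferase gene Dnmt3b (-0.72 ± 0.17, limma adjusted p = 0.0172). The third, Jarid2, fell by 0.33 ± 0.09, a call lost on leaving out any of 10 of 15 libraries (highest limma adjusted p = 0.077, without vehicle replicate 5), and Dnmt3b did not pass in the libraries over 5 M reads (0.0787). Cytosolic ribosomal protein genes were lower as a group (median -0.08, camera adjusted p = 0.000439, but adjusted p = 0.517 with an estimated correlation), with 0 of 77 passing, over the list alone too. DNA replication and S phase genes were lower (median -0.17, camera adjusted p = 0.00455, but adjusted p = 0.257 with an estimated correlation), with 0 of 40 passing on either adjustment. Cell junction and epithelial genes were higher (median 0.10, camera adjusted p = 0.00783, but adjusted p = 0.29 with an estimated correlation). Of 30, 1 rose, the plakoglobin gene Jup (0.42 ± 0.09), against 5 up and 1 down adjusted over the list alone. Without vehicle replicate 7 that list did not pass (camera adjusted p = 0.0529), and Jup did not in the libraries over 5 M reads (limma adjusted p = 0.0555). MicroRNA pathway genes were lower (median -0.12, camera adjusted p = 0.0328, but adjusted p = 0.257 with an estimated correlation), and the 1 of 22 that fell was Lin28a, also a let-7 target (2 fell adjusted over the list alone). That call was lost without Str let-7f replicate 9 (camera adjusted p = 0.0639), vehicle replicate 2 (0.0602) or vehicle replicate 3 (0.0557).

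In total 397 genes passed in Str let-7f against vehicle, 277 higher and 120 lower, of 15068 tested with limma. Of the 397 genes, 156 rose and 57 fell more than 2-fold. Of all genes tested, 2250 had an unadjusted limma p under 0.05, where chance gives 753. Of the lists, 10 passed (4 higher, 6 lower), 3 of them with an estimated correlation, and random splits of the same pools gave up to 12 lists. The remaining lists did not pass, with camera adjusted p of 0.0591 for replication-dependent histones, 0.105 for cholesterol synthesis and 0.124 for mitochondrially encoded genes. The value was 0.253 for Hippo and YAP targets, 0.458 for both ribosome biogenesis and the interferon response, and 0.484 for glycolysis, WNT and TGF-beta signalling, and fibroblast and stroma markers. It was 0.578 for imprinted genes and for insulin, IGF and mTOR signalling, 0.719 for Y-linked genes, 0.738 for nuclear-encoded oxidative phosphorylation, 0.784 for X inactivation and 0.997 for mitosis. Markers of other cells that a pool might hold did not pass either, at 0.601 for cumulus and granulosa, 0.677 for sperm and testis and 0.928 for blood and immune cells. Median, mean and test differed in sign for the epiblast, oocyte, glycolysis, mitosis, imprinted and FGF lists. In the 7 Str let-7f and 5 vehicle libraries over 5 M reads, chosen after seeing the data, 201 genes passed.

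At the doubled concentration known let-7 targets were also lower than in vehicle blastocysts, among them Lin28a, Trim71, Igf2bp1 and Nr6a1 as in Str let-7f. Lin28a stood at 723 ± 304 normalized counts (SD, n = 5) against 1597 ± 234 (n = 7), a log2 fold change of -1.21 ± 0.21 (SE; limma adjusted p = 0.00287). Trim71 stood at 1078 ± 266 against 1828 ± 142 (-0.79 ± 0.16, limma adjusted p = 0.00923), and Arid3b, an AT-rich DNA-binding protein gene, at 180 ± 61.1 against 391 ± 46.8 (-1.18 ± 0.24, limma adjusted p = 0.00923). For these 3 genes all 5 pools lay below every vehicle pool. Igf2bp1 fell by 0.46 ± 0.12 and Mycn, a MYC family gene, by 1.26 ± 0.30. Nr6a1 stood at -1.54 ± 0.38 (limma adjusted p = 0.0341), a call not recomputed without single libraries. Of 45 measured let-7 targets 6 fell and 0 rose, or 9 and 2 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00583, and adjusted p = 0.028 with an estimated correlation). Lin28b (-0.71 ± 0.45, limma adjusted p = 0.558), Arid3a (-0.45 ± 0.47, limma adjusted p = 0.77) and Hmga2 (0.02 ± 0.15, limma adjusted p = 0.974) did not pass. The call of Igf2bp1 was lost on leaving out any of 10 of 12 libraries (highest limma adjusted p = 0.122, without 2x Str let-7f replicate 4) and that of Mycn on leaving out any of 6 (highest 0.0983, without 2x Str let-7f replicate 3). In the libraries over 5 M reads, with 3 of 2x Str let-7f, Lin28a (limma adjusted p = 0.101), Trim71 (0.0567) and Arid3b (0.106) did not pass.

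Ppl rose from 286 ± 79.4 to 1561 ± 111 normalized counts in 2x Str let-7f (2.49 ± 0.17, limma adjusted p = 9.38e-09) and Gpnmb from 29.0 ± 26.2 to 677 ± 190 (4.82 ± 0.40, limma adjusted p = 1.56e-07). Myh14 rose by 3.83, Me1 by 1.20, Eppk1 by 2.11, Ckb by 0.84 and Dmkn by 1.70. Plec, which encodes the cytoskeletal linker plectin, rose from 11760 ± 1377 to 21300 ± 1646 (0.86 ± 0.10), and the atypical cadherin gene Fat1 from 5339 ± 664 to 9097 ± 647 (0.78 ± 0.09). Cbr2 had 340 reads over all 5 libraries against 11 in vehicle (5.53 ± 0.64). Nid2 fell from 1320 ± 261 to 317 ± 64.2 (-2.05 ± 0.20, limma adjusted p = 2.44e-06), and lower as well were Rcn1 (-1.92), Trim6 (-1.45), Ckap4 (-1.22), Golm2 (-0.80) and the tubulin gene Tubb5 (-0.77 ± 0.13). The neuronal tubulin gene Tubb3 had 8 reads in 3 of 5 libraries against 581 reads over all 7 vehicle libraries (-4.72 ± 0.79). In all 20 genes taken by smallest adjusted p, the 5 pools lay on the same side of every vehicle pool, which again follows largely from the choice. Golm2 and Tubb5 did not pass in the libraries over 5 M reads (limma adjusted p = 0.0747 and 0.0752).

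Primitive endoderm genes were lower in 2x Str let-7f too. Of 24, 10 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.93, camera adjusted p = 6.69e-14, and adjusted p = 0.028 with an estimated correlation). Cubn stood at 1075 ± 210 against 2690 ± 684 normalized counts (-1.30 ± 0.18, limma adjusted p = 0.000202), Sparc at 1362 ± 369 against 3067 ± 477 (-1.21 ± 0.21) and Lamb1 at 4570 ± 1392 against 9727 ± 1493 (-1.14 ± 0.20). Foxq1, a forkhead transcription factor gene, fell by 1.82 ± 0.33 (limma adjusted p = 0.00348; 0.127 in the libraries over 5 M reads). Gata6, Pdgfra and Sox17 did not pass, at 0.37 ± 0.20, -0.17 ± 0.20 and -0.26 ± 0.21. The epiblast (camera adjusted p = 0.706) and trophectoderm (camera adjusted p = 0.522) lists did not pass. Within the trophectoderm list Krt19 (1.65 ± 0.42) and Plac1 (0.83 ± 0.20) rose. These calls were lost on leaving out any of 10 and 9 of 12 libraries, with highest limma adjusted p of 0.127 for Krt19 (without 2x Str let-7f replicate 1) and 0.0897 for Plac1 (without 2x Str let-7f replicate 3).

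Transcripts of the 2-cell stage stood at 81.2 RPM in 2x Str let-7f against 30.6 in vehicle, a pooled ratio of 2.65 (exact permutation p = 0.00126, the smallest possible), with all 5 pools above every vehicle pool. The list was higher (median 2.54, or 3.29 with members at 0 vehicle reads at their bound; camera adjusted p = 1.51e-07, but adjusted p = 0.154 with an estimated correlation). Of 16 members, 1 rose over all genes and 8 adjusted over the list alone. That gene, Usp17lc (4.74 ± 1.23, limma adjusted p = 0.0466), lost its call on leaving out any of 11 of 12 libraries (highest 0.137, without 2x Str let-7f replicate 4). The 5 members without vehicle reads had 426 reads, at least 279-fold higher over the floor of 3 reads in the vehicle group, and the 3 families summed stood at 36.0 against 7.35 RPM (exact permutation p = 0.00126). Ooep rose by 1.31 ± 0.24 (limma adjusted p = 0.00422) and Khdc3 by 0.58 ± 0.13 (0.0231; 0.0891 without 2x Str let-7f replicate 4 and 0.0713 without replicate 5), while the oocyte and maternal list did not pass (median -0.04, camera adjusted p = 0.711).

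The integrated stress and unfolded protein response list did not pass in 2x Str let-7f (median -0.19, camera adjusted p = 0.119). Among the other lists, heat shock and oxidative stress genes were higher (median 0.19, camera adjusted p = 5.11e-05, but adjusted p = 0.0904 with an estimated correlation), with 3 of 27 rising and 8 adjusted over the list alone. Txnrd1 rose by 0.74 ± 0.14 (limma adjusted p = 0.00393), Srxn1, the sulfiredoxin gene, by 2.28 ± 0.51 and Gclc by 1.04 ± 0.27. The p53 targets were higher (median 0.35, camera adjusted p = 0.000395, but adjusted p = 0.151 with an estimated correlation), with 2 of 24 rising, or 7 adjusted over the list alone. They were Ccng1 (1.10 ± 0.14, limma adjusted p = 8.45e-05) and Perp (0.57 ± 0.13). Jun rose to 509 ± 125 normalized counts (1.47 ± 0.20, limma adjusted p = 0.00013) and the ERK feedback inhibitor gene Spry4 fell by 1.60 ± 0.41. Cytosolic ribosomal proteins (median -0.12, camera adjusted p = 0.000105, but adjusted p = 0.446 with an estimated correlation) were lower, with 0 of 77 genes passing on either adjustment. Replication-dependent histones (median -0.27, camera adjusted p = 0.000575, but adjusted p = 0.544 with an estimated correlation) had 1 of 43 lower on both adjustments, H2bc12 (-0.96 ± 0.24). DNA replication and S phase genes (median -0.19, camera adjusted p = 0.00246, but adjusted p = 0.215 with an estimated correlation) had 0 of 40 passing on either, and their call was lost without 2x Str let-7f replicate 2 (camera adjusted p = 0.0637). Cell junction genes (median 0.11, camera adjusted p = 0.0445, but adjusted p = 0.446 with an estimated correlation) had 2 of 30 higher, Jup (0.41 ± 0.10) and the desmoplakin gene Dsp (0.26 ± 0.07), or 4 adjusted over the list alone. That list did not pass without any of vehicle replicates 3, 6 and 7 and 2x Str let-7f replicates 1, 2 and 5 (highest camera adjusted p = 0.164, without vehicle replicate 7). Chromatin modifiers, lower in Str let-7f, did not pass here (median -0.11, camera adjusted p = 0.0789), though Dnmt3b fell by 0.78 ± 0.19. Several of these calls were lost on leaving out single libraries. Srxn1 did not pass without 2x Str let-7f replicate 5 (limma adjusted p = 0.0569) or replicate 4 (0.0525), and Perp did not without replicate 4 (0.0748), 3 (0.0502) or 5 (0.0512). Calls were lost on leaving out any of 10 of 12 libraries for Gclc (highest limma adjusted p = 0.118, without 2x Str let-7f replicate 2) and Jup (0.126, replicate 2), any of 11 for Spry4 (0.156, replicate 4), any of 12 for Dsp (0.101, replicate 5), any of 9 for H2bc12 (0.102, replicate 2) and any of 7 for Dnmt3b (0.117, replicate 4). Txnrd1 did not pass in the libraries over 5 M reads (limma adjusted p = 0.112).

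In total 285 genes passed in 2x Str let-7f against vehicle, 185 higher and 100 lower, and 1941 had an unadjusted limma p under 0.05. Of the 285 genes that passed, 122 rose and 64 fell more than 2-fold. Of the 33 lists, 9 passed (4 higher, 5 lower), 2 of them with an estimated correlation, and random splits of the same pools gave up to 11. The lists not named above had camera adjusted p of at least 0.119. Median, mean and test differed in sign for the oocyte, glycolysis, cholesterol, insulin and X inactivation lists. The count of genes fell to 144 without 2x Str let-7f replicate 5, 151 without replicate 3, 157 without replicate 4 and 188 without replicate 2, and to 176 and 181 without vehicle replicates 3 and 2. Without the 2 libraries under 2 M reads it was 185, and in the 3 libraries of 2x Str let-7f and 5 of vehicle over 5 M reads it was 68, both subsets chosen after seeing the data.

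With limma no gene was called between both mimic concentrations, while edgeR called 1 and DESeq2 11. Lin28a differed by 0.23 ± 0.21 on the log2 scale, Trim71 by 0.01 ± 0.15, Igf2bp1 by 0.12 ± 0.11, Hmga2 by -0.08 ± 0.14, Lin28b by 0.19 ± 0.44 and Arid3a by 0.00 ± 0.45. Primitive endoderm genes (median -0.07, mean 0.00, camera adjusted p = 0.857), genes of the 2-cell stage (median 0.23, camera adjusted p = 0.772) and let-7 targets (median 0.11, camera adjusted p = 0.441) did not pass. Of the 15068 genes tested with limma, 608 had an unadjusted p under 0.05, where chance gives 753. The smallest limma adjusted p was 0.126, for Szrd1, at 1023 ± 401 normalized counts (SD, n = 5) in 2x Str let-7f and 446 ± 66.8 (n = 8) in Str let-7f. Other values that did not pass were 3.30 ± 0.72 for Podn, 1.41 ± 0.31 for Sirt7, a deacetylase gene, 0.94 ± 0.21 for Map4k5 and 0.72 ± 0.17 for Aifm1. On the lower side they were -1.60 ± 0.32 for Acbd4, -0.95 ± 0.20 for the ubiquitin ligase gene Cbl, -0.99 ± 0.25 for Klhl24, -1.18 ± 0.32 for Fadd and -0.99 ± 0.27 for Arel1. None of the 33 lists passed (smallest camera adjusted p = 0.175, for mitochondrially encoded genes), and 3 had an unadjusted camera p under 0.05. These were mitochondrially encoded genes (0.0053) and replication-dependent histones (0.0137), both lower at the doubled concentration, and let-7 targets (0.0452). The let-7 targets were higher at the doubled concentration, with 30 of 45 members above 0. Median, mean and test differed in sign for the primitive endoderm, trophectoderm, mitosis, FGF, Hippo, WNT, Y-linked and cell junction lists. Without 2x Str let-7f replicate 2, 2x Str let-7f replicate 5 or Str let-7f replicate 3, 1 gene passed, and without Str let-7f replicate 3, 2 lists did. Changes of 2-fold and 4-fold were recovered in 29.9% and 60% of simulated genes for this comparison. Differences of 2-fold or less between the concentrations were thus mostly not detectable.

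Fold changes against vehicle at both concentrations were set side by side. Of the genes that passed, 146 rose at both, 56 fell at both and 0 went in opposite directions. They included Ppl, Gpnmb, Me1, Nid2, Cubn, Lin28a and Trim71. Independent lists of those sizes would share 3.40 and 0.796 genes. Since both comparisons share the vehicle libraries, unchanged groups with shared controls were simulated. For this, the group means of each gene were removed and all 20 libraries were shuffled over the 3 group labels. At most 1 gene was then called at both concentrations (mean 0.01). With the vehicle libraries split into disjoint sets, 46 genes were called at both (median of 35 splits, range 28 to 63). Across genes, which are not independent, the fold changes correlated with Pearson r = 0.7 and Spearman rho = 0.617. Simulated unchanged groups gave a mean r of 0.458 and up to 0.743, so this r lies within what shared controls can give. With split controls r was 0.361 (0.331 to 0.378). The covariance was 0.332 against a simulated mean of 0.134 and a highest of 0.218, a difference of 0.198, and it was 0.215 with split controls. Over the 480 genes called at either concentration, the median absolute difference between the concentrations was 0.20 on the log2 scale, with a median SE of 0.26. Adjusted over these genes alone, 4 differed.

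**Figure D5:**
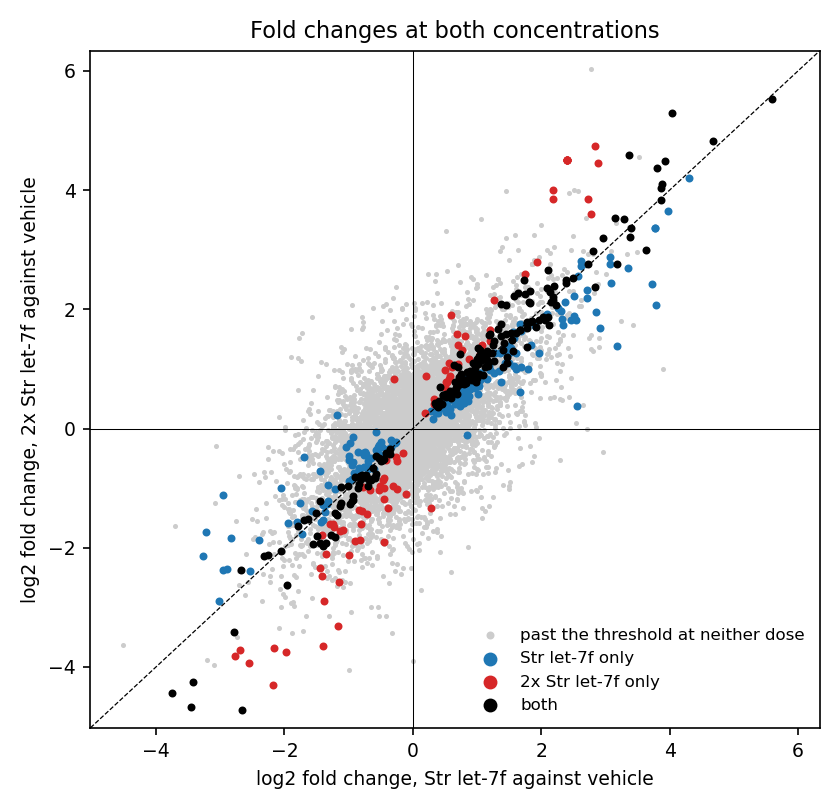
Log2 fold change against vehicle of 15068 genes in Str let-7f (x axis) and 2x Str let-7f (y axis), with the diagonal dashed. Black points are the 202 genes past the threshold at both concentrations, blue and red those past it at 1 of them, and grey those past it at neither.

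The mimic would pair with the 8-base site CTACCTCA, which matches its bases 2 to 8 followed by an A. On GENCODE M21 transcripts, Trim71 carried 4 such sites in a 3′ UTR of 5512 bases, at bases 166 to 173, 262 to 269, 3591 to 3598 and 3617 to 3624. Igf2bp1 carried 3 in 6337 bases, Nr6a1 3 in 4453 bases and Lin28a 2 in 2775 bases (bases 909 to 916 and 1547 to 1554). Lin28b, Hmga2 and Arid3a, whose levels did not pass, carried 1 each, Arid3b and Mycn 0, and Trim6 5. Sites of 7 bases, CTACCTC, those within the longer site included, numbered 4 each in Lin28b, Hmga2, Trim71 and Igf2bp1, 8 in Nr6a1 and 2 each in Lin28a and Arid3a. As a group, the 503 tested genes with a site had a mean log2 fold change that differed by -0.06 from that of the 12907 genes without, in Str let-7f (camera adjusted p = 0.328 over both concentrations, and adjusted p = 0.119 with an estimated correlation). Of the 406 control sequences, 18 gave a difference as low. In 2x Str let-7f the difference was -0.04 (camera adjusted p = 0.513, and adjusted p = 0.356 with an estimated correlation), and 37 of the 406 controls were as low. With sites of 7 bases included, 1482 genes had a site and the difference was -0.0143 in Str let-7f and -0.0137 in 2x Str let-7f. A difference of the whole group was not past the threshold of this test at either concentration.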

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

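The tests of depth, cell share, near-identical copies, oocytes and shared vehicle pools below were chosen only after the results were seen, and those of batch and of other splits of the pools before. A single pool stood apart from the rest of its group in 9 of 138 groups tested over 43 genes and 3 library measures, where chance gives about 1 in 20, or 6.9. For Lin28b vehicle replicate 6 was at 16.05 normalized counts, the others at 33.9 to 53.78. For Hmga2 Str let-7f replicate 2 was at 1587 (others 2091 to 2524) and 2x Str let-7f replicate 1 at 1494 (2157 to 2438). For Trim6 2x Str let-7f replicate 4 was at 423.5 (694.9 to 842). For Ckap4 Str let-7f replicate 1 was at 1061 (563.7 to 738.7) and 2x Str let-7f replicate 1 at 984 (459.6 to 572.1). For Eppk1 Str let-7f replicate 2 was at 274.9 (516.8 to 840.7), for Szrd1 Str let-7f replicate 6 at 594.9 (369.1 to 461) and for Map4k5 vehicle replicate 7 at 610 (339.8 to 431.5).

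The entry without a gene name, which entered no comparison, averaged 4407.9 ± 922 normalized counts (SD, n = 8) in Str let-7f and 3400.2 ± 579.8 (n = 7) in vehicle (exact permutation p = 0.0274), with 3 of 8 pools above every vehicle pool. In 2x Str let-7f it averaged 3706 ± 755 (exact permutation p = 0.42). What the entry holds is not stated.

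Primitive endoderm genes were lower at both concentrations. Library depth is argued against as the whole cause, since among libraries over 5 M reads the smaller of both mean log2 differences of the list was -0.8457. If Gata6, Pdgfra and Sox17 were expressed mainly in primitive endoderm cells, a lower share of such cells should lower them with the rest. Pooled embryos do not show in which cells these genes were expressed. These 3 differed from vehicle by -0.09 and -0.02 on average at the lower and doubled concentration, and the other 21 members by -1.03 at both (exact permutation p of the difference = 0.00155 and 0.00126). The 3 genes were set apart after their values were seen, so this split decides nothing, and fewer such cells cannot be told apart from lower expression in them, an effect of the mimic or of any injected small RNA that was not tested.

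Genes of the 2-cell stage were higher in both mimic groups, in 6 of 8 and 5 of 5 pools above every vehicle pool. Members without vehicle reads entered the list only through mimic pools, which by itself favours a higher list. Among libraries over 5 M reads the rate of the whole list was still higher, with a median of 98.2 RPM in Str let-7f (n = 7) and 68.6 RPM in 2x Str let-7f (n = 3) against 30.0 RPM in vehicle (n = 5; exact permutation p = 0.0391 and 0.0179, the latter the smallest possible), which argues against depth as the whole cause. The sum over the measured copies of 3 gene families differed from vehicle at both concentrations (larger exact permutation p = 0.0295). This argues against a mere exchange of reads among those measured copies. Copies without vehicle reads could enter that sum only through mimic pools, and an exchange with copies not measured here was not tested. Oocytes or arrested embryos in mimic pools cannot be told apart from expression in the blastocysts, since the oocyte and maternal list had a camera adjusted p of 0.523 and a mean log2 fold change of -0.05 in Str let-7f, where its members Ooep and Khdc3 rose and Kpna7 fell (261 reads in vehicle, 4 in Str let-7f). An effect of the mimic itself stays open and untested, since pooled embryos do not separate these sources.

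Fold changes were alike at both concentrations. With disjoint vehicle libraries for each comparison, at least 28 genes were called at both, against at most 1 in simulated unchanged groups, which argues against shared vehicle libraries as the whole cause. A batch between vehicle and mimic pools cannot be told apart from the mimic, since 0 label tags name a batch, run or date. An effect of let-7f at both concentrations and a response to any injected RNA, for which no control group exists, both stay open and untested.

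Other splits of the same pools were counted, 100 per comparison, the real one included. For genes changed, only the real split gave as many in Str let-7f (397, highest other 1) and in 2x Str let-7f (285, highest other 40). A random division of these pools is thus an unlikely source of either count. The splits treat pools as exchangeable, so they cannot exclude a day or female shared by pools of a group, which the labels do not name. For the number of lists chance cannot be excluded, since 7 splits gave as many in Str let-7f (10, highest other 12) and 8 in 2x Str let-7f (9, highest other 11). For genes with a let-7 site, 4 splits gave a mean difference as large in Str let-7f (0.0556, highest other 0.0741), and 20 did in 2x Str let-7f (0.0371, highest other 0.0751). The share in Str let-7f is under 1 in 20 for that concentration alone, but it is not adjusted over both, and camera gave an adjusted p of 0.328, so chance is not taken as excluded for either. Between both concentrations the real counts were 0 genes and 0 lists (highest others 2 and 11), which all 100 splits must reach, so these splits say nothing about chance.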

How the results depend on the processing

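The subsets of libraries by depth were the only alternatives chosen after seeing the data. Of 89 results of named genes past the threshold, 50 stayed past it under every alternative run, and over 2443 alternatives 2149 kept the call, 294 lost it and 0 reversed. Of 106 results of named genes not past it, 122 of 2866 alternatives moved past it and 40 reversed. Of 19 list calls, 5 held under every alternative, 29 of 353 alternatives ended one, and 11 other lists passed under at least 1.

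With array weights 617 genes passed in Str let-7f and 647 in 2x Str let-7f against vehicle. DESeq2 called 767 and 621, and 11 between both concentrations, where edgeR called 1, and the cause was not tested. In libraries over 5 M reads 201 and 68 passed, and without the 2 libraries under 2 M reads 185 did in 2x Str let-7f, with fewer samples. Leaving out each library gave 144 to 273 genes in 2x Str let-7f against vehicle, and 0 to 1 genes and 0 to 2 lists between both concentrations. With an estimated correlation 3 lists passed in Str let-7f and 2 in 2x Str let-7f.

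Deviations of pools that share a replicate number correlated weakly (14 pairs, r from -0.007 to 0.092). Pairs with other numbers had a median r of -0.008 (-0.109 to 0.117), so a weak shared deviation cannot be excluded. The labels do not say that the numbers mark a shared day, so they were not taken to pair the pools. With the number as a block, 293, 277 and 0 genes passed in the 3 comparisons, and 12, 12 and 2 lists.

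Reversed values were all of genes not past the threshold, and the cause was not tested. Between both concentrations Trim71 stood at -0.0002 and Arid3a at -0.0039 with TMM scaling. With the replicate block Lin28b was -0.3678, Trim71 -0.0818 and Arid3a -0.5254. With the Y-linked covariate Trim71 was -0.0433, Arid3a -0.0348 and Ddx3y 0.0512. With array weights Trim71 was -0.1217, Ddx3y 0.2059 and Eif2s3y 0.3229. Without the 2 libraries under 2 M reads Lin28b was -0.0713 and Trim71 -0.017, and in libraries over 5 M reads Trim71 was -0.1182 and Arid3a -0.2977. Leaving out each library gave -0.0205 to 0.3777 for Lin28b, -0.1545 to 0.0412 for Hmga2, -0.0901 to 0.1182 for Trim71, -0.2972 to 0.1835 for Arid3a, -0.2622 to 0.1904 for Ddx3y and -0.5111 to 0.1451 for Eif2s3y. In 2x Str let-7f against vehicle Hmga2 was -0.0324 without the 2 libraries under 2 M reads and -0.0119 in those over 5 M. There, leaving out each library gave -0.0495 to 0.1441 for Hmga2 and -0.1085 to 0.5477 for Eif2s3y.

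Depth limits the genes of few reads: a floor of 3 reads was 1.94 RPM in the shallowest library and 0.0511 RPM in the deepest.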

Other observations

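The Fisher test and the genes named in the next paragraph were chosen after the data were seen, and the test matched for UTR length was set before its result was. Some members of lists that did not pass as groups passed singly. They were chosen after their values were seen and not recomputed without single libraries. Tgfbr2, a TGF-beta receptor gene, rose by 1.16 in Str let-7f (limma adjusted p = 0.0146) and 1.30 in 2x Str let-7f (limma adjusted p = 0.0228), and the WNT effector gene Tcf7l1 fell by 1.33 in Str let-7f (limma adjusted p = 0.0285). The imprinted gene Plagl1 rose by 1.80 (limma adjusted p = 0.00775) and Dhcr7, of cholesterol synthesis, by 0.83 (limma adjusted p = 0.0134), both in Str let-7f. Cdc20, an activator of the anaphase-promoting complex, rose by 0.34 (limma adjusted p = 0.0447) and 0.43 (limma adjusted p = 0.0339).

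Genes with the 8-base let-7 site were more common among genes that fell in Str let-7f. Of 503 genes with the site 11 fell (2.19%), against 105 of 12907 without (0.81%; Fisher's exact p = 0.00419, odds ratio 2.73). They were Lin28a, Acsl6, Trim6, Trim71, Igf2bp1, Nr6a1, Ddx19a, Rbms1, Tmprss2, Dpp3 and Npc2, of which the last 5 were named after their values were seen. In 2x Str let-7f 7 of 503 fell, against 92 (Fisher's exact p = 0.101). These tests, and the one matched for UTR length below, treat genes as independent, which they are not. Their p-values are not adjusted over both concentrations or over sites of 8 and 7 bases. With sites of 7 bases included the difference was lost in Str let-7f, with 18 of 1482 (1.21%) against 98 of 11928 (0.82%; Fisher's exact p = 0.135), and 14 against 85 fell in 2x Str let-7f (Fisher's exact p = 0.332).

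Genes with a site have longer 3′ UTRs, with a median of 2547 bases against 1150, so the test was repeated within 5 classes of UTR length. The odds ratio was 2.58 (95% confidence interval 1.22 to 4.96, exact p = 0.00719) in Str let-7f, which argues against UTR length as the whole cause, and 2.05 (0.784 to 4.55, exact p = 0.0931) in 2x Str let-7f, where length cannot be told apart. Direct repression of a small set of genes with a site, rather than of all genes with a site, may be a hypothesis for Str let-7f, and it rests on the 8-base site alone. A shift of the 503 genes as a whole was not past the threshold of camera.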
